A study of Mus musculus with 2 samples.

How the data were processed

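Per the labels' protocols, total RNA was extracted from mouse liver and 250 ng of it was turned into biotin-labelled cRNA by the standard Affymetrix procedure. The deposited values are probe-set intensity values on a linear scale, and the submitters' processing notes name MAS5, an algorithm that summarises the probes of a probe set into a signal. The settings of that step, detection calls and the genome build are not given in the sources used here. On the values themselves, the mean after trimming 2% from each end was 500.004 on both arrays, which shows that each array had been scaled to a common level before deposit. The medians of the arrays were 71.4 for the wild type and 76.2 for the knockout. Groups were taken from the genotype labels: 1 array of a Pik3ca transgenic, Kdm3a wild-type mouse and 1 of a Pik3ca transgenic, Kdm3a knockout mouse. Whether an array holds RNA of a single animal is not stated.

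The table held 45101 probe sets, of which 64 were controls. Genes were named through the platform annotation: 34945 probe sets named 1 gene, 932 named several and 9160 were not named in the annotation used here. Gene identifiers of 34754 of them were found in a RefSeq gene table of assembly GRCm38.p6, used for current names alone. Probe sets naming several genes or none entered no gene comparison.

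The floor, filter, size rule, gene lists, cell type markers and named-gene rule were fixed before the data were examined. Values below the floor of 46.5, the 40th percentile of all values pooled over both arrays, were raised to it, and a ratio with a floored value is a bound, written as "at least". Probe sets were kept if their mean signal over both arrays was at or above the median of such means, 73.7. This left 19800 probe sets and 11693 genes. A gene with several kept probe sets took the value of the brightest. The measure was the log2 ratio of knockout over wild type, and genes were counted at a difference of at least 2-fold. With 1 array per group there was no test, no p-value and no error between animals. The single repeat measurement was the SD of log2 ratios between probe sets of the same gene, 0.446 over 4958 genes, which covers error within an array alone. Of the 2-fold genes with several kept probe sets, 95 of 119 higher and 286 of 339 lower genes had every probe set in the same direction.

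Each list's median log2 ratio was ranked among 10000 random lists of the same size, each member replaced by a gene drawn from the 200 genes nearest in mean signal. Lists with fewer than 5 measured genes were not ranked. There were 26 gene lists: AP-1 subunits and partners, AP-1 targets, immediate early genes, hypoxia and glycolysis, de novo lipogenesis, lipid droplet and PPAR-gamma, PPAR-alpha and fatty acid oxidation, cholesterol, bile acids, gluconeogenesis and insulin response, PI3K-AKT components, xenobiotic and glutathione metabolism, cell cycle, fetal liver and liver tumour genes, pericentral and periportal hepatocyte genes, acute phase, interferon response, unfolded protein and integrated stress response, oxidative phosphorylation, ribosomal proteins, circadian clock, male-biased and female-biased liver genes, sex chromosome genes and H3K9 methylation enzymes. Markers of 11 cell types were hepatocyte, macrophage, stellate cell and fibroblast, endothelial, cholangiocyte, T and NK cell, B and plasma cell, neutrophil, erythroid, adipocyte and pancreatic acinar cell. The lists were written from general knowledge of liver biology.

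Named genes were Kdm3a, Pik3ca, the 10 highest and 10 lowest log2 ratios among genes above the floor on both arrays whose kept probe sets went the same way, the 5 highest bounds in each direction, and up to 2 highest and 2 lowest members of each list. Predicted genes of unknown function were passed over. The genes Afp, Anxa2, S100a8, C1qa, C1qb and Ctss in the results, and the gene families, clock gene lists and single genes in the closing section, were chosen after values were seen. The further lists of resident and recruited macrophage genes were written after the values of the macrophage markers had been seen, but before those of their own genes.

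Alternatives fixed before the data were examined were centring on array medians, quantile normalization, loess on signal with a span of 0.300, no filter, a filter at the 70th percentile, floors at the 20th and 60th percentile, no floor, the mean of all kept probe sets, leaving out probe sets by name ending, and size rules of 1.5-fold and 3-fold. Probe sets left out by name ended in _s_at, _x_at, _a_at or _f_at and are called cross-matching here. The ending alone was used, so such a probe set need not match a second gene. Scaling on the hybridisation controls and on the poly-A controls was added after seeing the data. For each alternative, a list median was called moved if it differed by more than the half-width of the middle 95% of its random lists. That yardstick was chosen after a first, narrower one, the SD of the random lists, had been run and its outcome seen. The steps were tested on simulated arrays with 11851 genes and known differences. Of genes set at a log2 difference of 1.5 in the simulation of this comparison, 94% of 50 were called higher, and of those set at -1.5, 86.7% of 45 were called lower. All genes set at 3 or -3 were called, and 2.49% of 11660 unchanged genes passed 2-fold by the simulated error, which was set from the probe-set spread and leaves out differences between animals. The simulated error was the same at every signal, so that share does not give the rate for dim genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

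The 3' over 5' signal ratio of the Gapdh controls was 0.701 in the wild-type and 0.654 in the knockout array, that of the actin controls was 1.85 and 1.99, and 59.0% and 61.0% of probe sets lay above the floor. The 3 control probe sets for 18S ribosomal RNA differed, at 1.74-fold to 1.89-fold higher signal in the knockout array, and the reason was not tested. Across kept probe sets, which are not independent replicates, the log2 signals of the arrays had a Pearson correlation of 0.935.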

Results

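Gene expression was measured in precancerous liver tissue of mice that carried a Pik3ca transgene in hepatocytes, the gene of the catalytic subunit of phosphoinositide 3-kinase. The mice were either wild type or knockout for Kdm3a, which encodes a demethylase of histone H3 lysine 9. The comparison asks what the loss of Kdm3a goes with in liver in which this kinase pathway is activated, before tumours form. Each genotype was represented by 1 Affymetrix expression array, so 2 arrays were compared and their number limits the precision. No difference given here has a replicate check, no test was possible, and values describe these arrays and not the genotypes. Ratios are log2 of the knockout signal over the wild-type signal.

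Kdm3a itself was 11.7-fold lower in the knockout array. Its signal was 719.9 in the wild-type array and 61.6 in the knockout array, which is 8.56% of the wild-type value. The gene was read by 1 probe set, and whether that probe set lies inside the deleted part of the gene is not known here, so it is a limited check of the labels. Pik3ca, carried as a transgene by both mice, had a signal of 1069 in the wild-type array and 1107 in the knockout array, a log2 ratio of 0.05. Its 4 other kept probe sets had log2 ratios from -0.54 to -0.14. Whether any Pik3ca probe set reads RNA of the transgene is not known here, so these values do not compare transgene levels.

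In the knockout array, genes of fetal and transformed liver, of matrix-producing cells and of bile duct cells were lower, and genes of periportal hepatocytes and genes known to be higher in male liver were higher. Ly6d, a small surface protein, was 25.2-fold lower, Cbr3, a carbonyl reductase, was 21.7-fold lower, and Lcn2, an iron-carrier-binding protein secreted by injured liver, was 12.9-fold lower. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, was 7.36-fold higher, Elovl3, a fatty acid elongase, was 7.26-fold higher, and Hal, the histidine-degrading ammonia lyase, was 6.95-fold higher. Of 11693 genes compared, 448 were at least 2-fold higher in the knockout array and 1048 were at least 2-fold lower. Lower genes thus made up 70.1% of those past 2-fold, against 52.3% with the arrays scaled on their poly-A controls and 80.6% with scaling on their hybridisation controls, both chosen after seeing the data. The excess of lower genes depended on signal. Among the 2339 genes of highest signal, 105 were higher and 103 lower, against 191 and 347 among the 2339 of lowest signal. Differences of at least 8-fold were found for 41 lower genes and 6 higher genes.

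The other genes with the lowest ratios measured above the floor on both arrays were Gpnmb, a glycoprotein of lipid-laden macrophages (-4.12), the glutathione transferase Gstm3 (-4.09), the mitotic spindle component Haus8 (-3.70), Gipc2 (-3.68), the macrophage elastase Mmp12 (-3.61) and the fibrillar collagen Col3a1 (-3.56). The other highest were the serpin pseudogene Serpina4-ps1 (4.01), the immunoglobulin heavy chain Ighm (3.44), the major urinary protein Mup10 (3.35), Fmr1nb (2.98), Cnmd (2.77), the kinase Cdc42bpb (2.76) and Etnppl (2.64), a phospho-lyase of phosphoethanolamine. Serpina4-ps1, Mup10, Ighm and Gstm3 have near-identical relatives that the same probes could read, and the 5 probe sets of Ighm ranged from 0.19 to 3.44. Among genes with a value at the floor on a single array, the lowest were Cpe, a prohormone-processing carboxypeptidase (at least 61.7-fold lower), Apela (at least 38.2-fold), the collagenase Mmp13 (at least 20.9-fold), the tubulin Tubb2b (at least 18.4-fold) and the trypsin inhibitor Spink1 (at least 15.6-fold). The highest were the macrophage scavenger receptors Cd163 (at least 23.9-fold higher) and Marco (at least 6.01-fold), followed by Tex12 (at least 5.86-fold), Timd4 (at least 4.86-fold) and Clec2h (at least 4.71-fold).

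**Figure D1:**
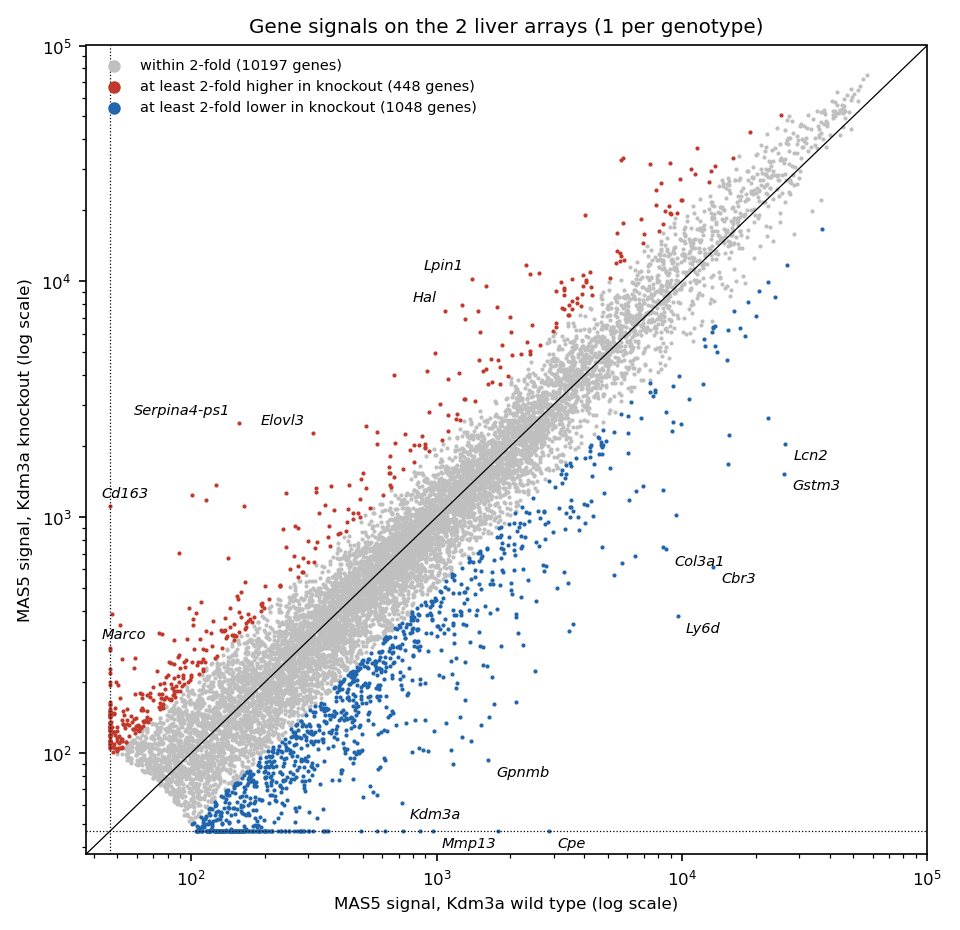
Signal of each compared gene on the knockout array (vertical axis) against the wild-type array (horizontal axis), MAS5 signal on log axes, 1 array per genotype; the diagonal marks equal signal and the dotted lines the floor of 46.5. 448 genes at least 2-fold higher in the knockout array are red and 1048 at least 2-fold lower are blue, with Kdm3a at 719.9 and 61.6.

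Of the 22 measured genes of fetal liver and liver tumours, 19 were at least 2-fold lower, 0 were higher and 3 lay within 2-fold. Besides Ly6d and Cbr3, the list held the alpha-fetoprotein gene Afp (-1.91) and Anxa2 (-3.23), both named after their values were seen. Igf2bp3 (0.15) and Mdk (0.06) lay within 2-fold. The list's median log2 ratio was -2.05, and all 10000 random lists of genes of similar signal had higher medians. Bile duct cell markers were lower alongside this list, and 5 of its listed genes stand on another list too. Of 14 measured cholangiocyte markers, 13 were at least 2-fold lower, or 9 with scaling on the poly-A controls. Their median was -1.66, again below all random lists. The surface protein Cd24a (-3.40) and the tetraspanin Tspan8 (-2.96), both also on the fetal and tumour list, had the lowest ratios of the markers. Krt23 (0.04) was the marker within 2-fold. The 3 kept probe sets of Tspan8 went both ways, from -2.96 to 0.69.

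Of 22 measured stellate cell and fibroblast markers, 12 were at least 2-fold lower and 0 were higher, with a median of -1.44 that lay below all random lists. Col3a1 and Col1a2 (-3.21), which encode fibrillar collagens, had the lowest ratios, and Ecm1 (0.88) the highest. Endothelial markers differed less: 1 of 19 was at least 2-fold lower, namely Vwf (-1.20), the median was -0.30, and 261 of the 10000 random lists had lower medians. Ehd3 (0.59) was highest. All 14 hepatocyte markers had a positive ratio, 11 of them after quantile normalization or loess, with a median of 0.40 against 0.32 for genes of similar signal. Among them, 1 of 14 reached 2-fold, the tyrosine-degrading dioxygenase Hpd (signals of 25381 in the wild-type and 50886 in the knockout array), against 2 with scaling on the poly-A controls and 0 under the other scalings. Ahsg (0.18) was lowest.

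Macrophage markers went both ways. Of 20 measured, 10 were at least 2-fold lower, 3 were at least 2-fold higher and 7 lay within 2-fold, against 6, 4 and 10 with scaling on the poly-A controls, and the median of -1.01 was below all random lists. The lower markers included Gpnmb and the lipid receptor Trem2 (-2.38). Among them were also the complement genes C1qa (-1.13) and C1qb (-1.37) and the cathepsin Ctss (-1.08), named after their values were seen. The higher ones were Cd163, Marco and Timd4, receptors of resident liver macrophages, which were all below the floor in the wild-type array. They passed the filter through their knockout signal alone, so with this floor and filter they could not lie within 2-fold.

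Lymphoid and other cell markers were few. Of 9 measured T and NK cell markers, 3 were at least 2-fold lower, among them the NK receptor Klrd1 (-1.63) and Thy1 (-1.31), a marker also of fibroblasts; the highest was Gzma (0.80). The median of -0.79 had 101 of 10000 random lists below it, but it was 0.00 with the floor at the 60th percentile. Of 6 B and plasma cell markers, 2 were higher, Ighm and the antibody joining chain Jchain (1.99), and 1 was lower, Cd22 (-1.57), with a median of 0.27 and 892 random lists above it. Of 8 neutrophil markers, 3 were lower, Lcn2, S100a9 (-2.18) and S100a8 (-1.73), and 1 was higher, Mmp9 (1.33), with a median of -0.14 and 3285 random lists below it. Too few genes were measured for a rank among erythroid (3), adipocyte (2) and pancreatic acinar (3) markers. Their medians were -0.17, -1.12 and 0.80. Tspan33 (1.52), Fabp4 (-2.80) and Prss2 (at least 4.17-fold higher) had the largest differences, and the 2 probe sets of Prss2 differed, at 0.07 and 2.06.

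**Figure D2:**
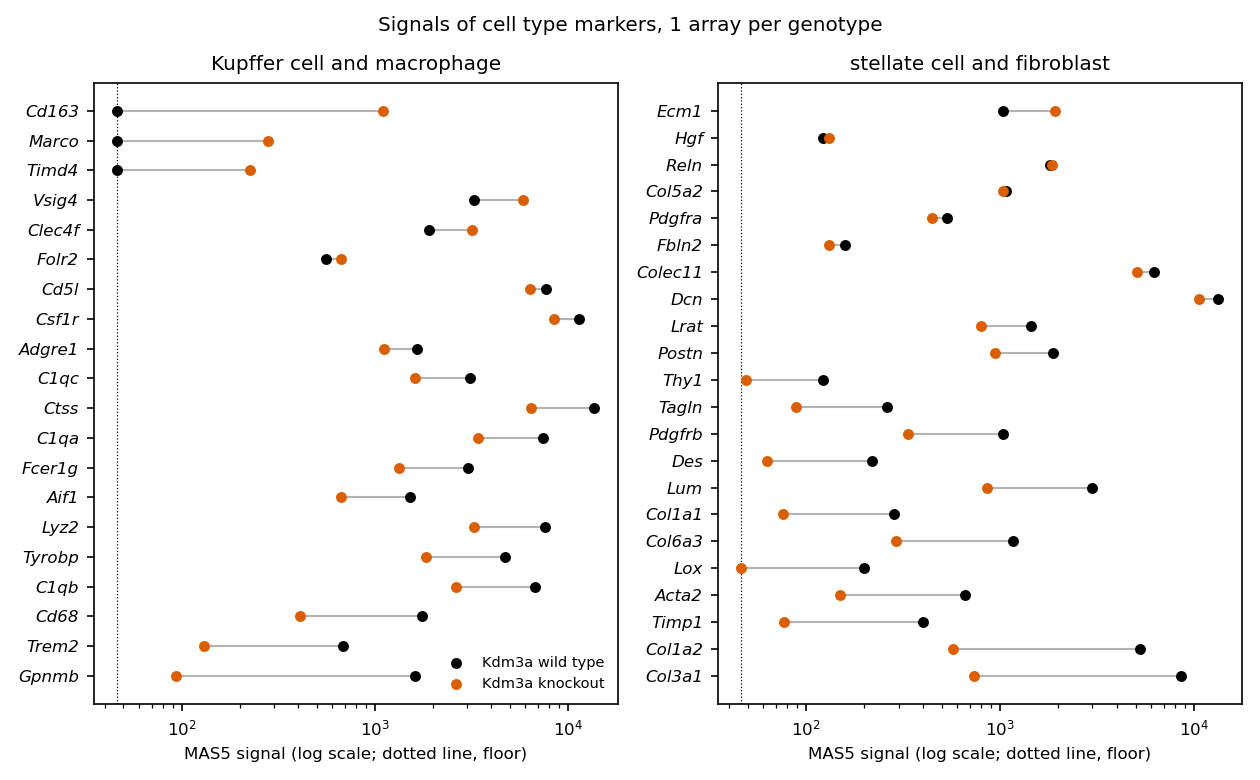
MAS5 signal (log axis) of each measured macrophage marker (left) and stellate cell and fibroblast marker (right) on the wild-type array (black) and the knockout array (orange), 1 array per genotype; the dotted line is the floor of 46.5. Macrophage markers go both ways, from a log2 ratio of -4.12 for Gpnmb to a bound of 4.58 for Cd163, and fibroblast markers lie mostly lower in the knockout array, around a median of -1.44.

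AP-1, the transcription factor built from JUN, FOS and ATF proteins, had 5 of 15 measured subunits and partners at least 2-fold lower and 0 higher. Atf3 (-2.94) and Jun (-1.61) had the lowest ratios, and Batf2 (0.79) the highest. Their median was -0.62, with 16 of 10000 random lists lower. Of 26 genes widely described as AP-1 targets, 17 were at least 2-fold lower and 2 higher. The matrix proteases Mmp13 and Mmp2 (at least 12.3-fold lower) had the lowest ratios, and Mmp9 and the growth factor receptor Egfr (1.20) were the higher genes. The median of -1.62 lay below all random lists, and 12 of the listed genes stand on another list too, some of them markers of fibroblasts or neutrophils. Among 21 immediate early genes, 8 were at least 2-fold lower and 0 higher, with a median of -0.60 below all random lists. Ier3 (-3.44) and Klf6 (-2.41) were lowest, and Btg1 (0.42) was highest.

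All 29 measured interferon response genes had a negative ratio, and 11 were past 2-fold, against 27 and 7 with scaling on the poly-A controls. Oasl2 (-2.46) and Ifit2 (-1.86), which encode antiviral proteins, were lowest, and Irf9 (-0.12) was nearest to 0. The median of -0.80 lay below all random lists. Of 29 acute phase genes, 8 were at least 2-fold lower and 2 higher. Lcn2 and the orosomucoid Orm2 (-3.20) were lowest, while Hamp (2.53), the iron hormone hepcidin, and Saa4 (1.42) were the higher genes. The acute phase median of -0.14 lay below that of 9999 of 10000 random lists, whose own median was 0.19; with scaling on the poly-A controls it was above 0, at 0.043. Cell cycle genes were at least 2-fold lower in 13 of 25 cases and higher in 1. The topoisomerase Top2a (at least 5.65-fold lower) and cyclin Ccna2 (at least 4.34-fold lower) had the lowest ratios and the thymidine kinase Tk1 (1.29) the highest. Their median of -1.04 lay below all random lists, but among the 10 genes kept with a filter at the 70th percentile of signal it was -0.28, at percentile 9.23.

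Genes of periportal hepatocytes, which handle nitrogen and amino acids, were at least 2-fold higher in 10 of 19 cases and lower in 1. The higher genes numbered 8 after quantile normalization and 11 with scaling on the poly-A controls. Hal and Etnppl were highest and Cdh1 (-1.66), a cadherin that is also a bile duct cell marker, was lowest. The median was 1.12, above all random lists. Of 22 pericentral genes, 3 were higher, or 7 with scaling on the poly-A controls, and 1 lower, among them the ornithine aminotransferase Oat (1.61), the drug-oxidising Cyp1a2 (1.15) and the claudin Cldn2 (-1.20). Their median was 0.41, with 14 of 10000 random lists above it. Of 15 genes known to be higher in male liver, 10 were at least 2-fold higher and 0 lower. With scaling on the hybridisation controls, 7 of 14 were higher and 1 was lower. Elovl3 and the organic anion carrier Slco1a1 (2.37) led, Nat8f5 (-0.87) was lowest, and the median of 1.20 was above all random lists. Of 16 genes known to be higher in female liver, 3 were higher, among them Hamp2 (2.57) and Cyp2b10 (1.98), and 1 was lower, the lipoprotein lipase Lpl (-1.87). Their median of 0.26 had 188 random lists above it and lay inside the middle 95% of random lists under several settings, for example at percentile 95.4 after quantile normalization. The 4 measured sex chromosome genes had log2 ratios by their brightest probe sets from -0.20 for Xist to 0.24 for Eif2s3y, and a second probe set of Uty stood at -0.60. The Y-linked Eif2s3y had signals of 2468 in the wild-type and 2906 in the knockout array, and Uty 814 and 813. Xist had 83 and 72, near the floor, and its other probe sets lay below the floor on both arrays. Male tissue on both arrays would give such signals.

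Bile acid genes were at least 2-fold higher in 5 of 25 cases and lower in 1, with a median of 0.44 and 5 of 10000 random lists above it. Slco1a1 and the oxysterol hydroxylase Cyp7b1 (2.05) were highest and the efflux pump Abcc4 (-2.27) was lowest. Cholesterol synthesis and uptake genes had 2 of 20 higher, Tm7sf2 (1.54) and Ebp (1.18), which act late in the pathway, and 1 lower, the squalene epoxidase Sqle (-1.37). The cholesterol median was 0.45, above all random lists, but 0.22 at percentile 96.7 when all kept probe sets of a gene were averaged. Gluconeogenesis and insulin response genes had 5 of 21 higher, including Igfbp2 (1.51) and the glycogen-targeting subunit Ppp1r3c (1.42), and 1 lower, Igfbp1 (-1.37). Their median was 0.36, at percentile 98.5, and at percentile 93.2 after loess scaling. Among xenobiotic and glutathione genes, 9 of 34 were higher and 5 lower, and the median of 0.16 had 4607 random lists below it. The cytochrome P450 genes Cyp2c37 (2.53) and Cyp2c54 (2.24), which have close relatives, were highest, and Gstm3 and the sulfiredoxin Srxn1 (-2.66) were lowest. The 4 kept probe sets of Srxn1 ranged from -2.66 to -0.39.

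Of 37 respiratory chain and ATP synthase genes, 36 had a positive ratio, 34 after quantile normalization or loess, and 0 reached 2-fold, 1 with scaling on the poly-A controls. Their median was 0.51 against 0.25 for genes of similar signal, with 10 of 10000 random lists above it. Sdhb (0.90) was highest and Ndufa2 (-0.04) lowest. Of 28 ribosomal protein genes, 28 lay within 2-fold, 27 with scaling on the hybridisation controls. Their median was -0.02 against 0.28 for genes of similar signal, a position below 9996 random lists; it was 0.17 with scaling on the poly-A controls, and at percentile 4.49 without cross-matching probe sets. Rpl14 (-0.96) was lowest and Rps2 (0.24) highest. Clock genes had 1 of 18 at least 2-fold higher, the repressor Nfil3 (1.35), and 0 lower; Clock (-0.61) was lowest. Their median of 0.29 stood at percentile 99.4, and at percentile 91.3 without cross-matching probe sets.

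In lipid metabolism, lipid droplet and PPAR-gamma genes were lower in 8 of 22 cases and higher in 0, with a median of -0.51 below all random lists. The fatty acid binding protein Fabp4 and Lpl were lowest and the lipase Lipe (0.43) was highest. The 3 kept probe sets of Fabp4 ranged from -2.80 to -0.98. De novo lipogenesis genes had 1 of 26 higher, Lpin1, and 2 lower, the desaturase Scd2 (-2.77) and the fatty acid synthase Fasn (-1.02). With scaling on the hybridisation controls 4 were lower, and with scaling on the poly-A controls 1 was lower and 2 were higher. Their median was -0.09, at percentile 4.38. It was -0.23 at percentile 0.47 after quantile normalization, and 0.09 with scaling on the poly-A controls. Fatty acid oxidation and PPAR-alpha genes had 4 of 36 lower, including the hormone Fgf21 (-3.54) and the kinase Pdk4 (-2.74), 0 higher, and a median of 0.06 at percentile 12.7. Without cross-matching probe sets, that list stood at percentile 0.65. Ppargc1a (0.59) was its highest gene. Hypoxia and glycolysis genes were lower in 5 of 26 cases and higher in 0, with a median of -0.36 and 11 random lists below it. The pyruvate kinase Pkm (-1.70) and phosphofructokinase Pfkp (-1.59) were lowest and Higd1a (0.67) highest, though its 3 probe sets ranged from -0.67 to 0.67.

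All 21 measured components of the PI3K-AKT pathway lay within 2-fold, all but 1 with scaling on the hybridisation controls, with a median of -0.05 and 4272 random lists below it. Mtor (-0.89) and Sgk1 (-0.78) were lowest and Pik3cd (0.38) highest, but the probe sets of Mtor and of Pik3cd went both ways. Of 14 other enzymes of H3K9 methylation, 1 was lower, the hairless gene Hr (-1.82), and 0 higher. Their median was -0.09 and 4611 random lists were lower. Kdm3b (0.27), the close relative of Kdm3a, and the methyltransferase Ehmt1 (0.28) were highest. Genes of the unfolded protein and integrated stress responses had 4 of 23 lower and 0 higher, with a median of -0.16 and 401 random lists below it. With scaling on the poly-A controls that median was 0.03. Fgf21 and the asparagine synthetase Asns (-2.76) were lowest and Herpud1 (0.47) highest.

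**Figure D3:**
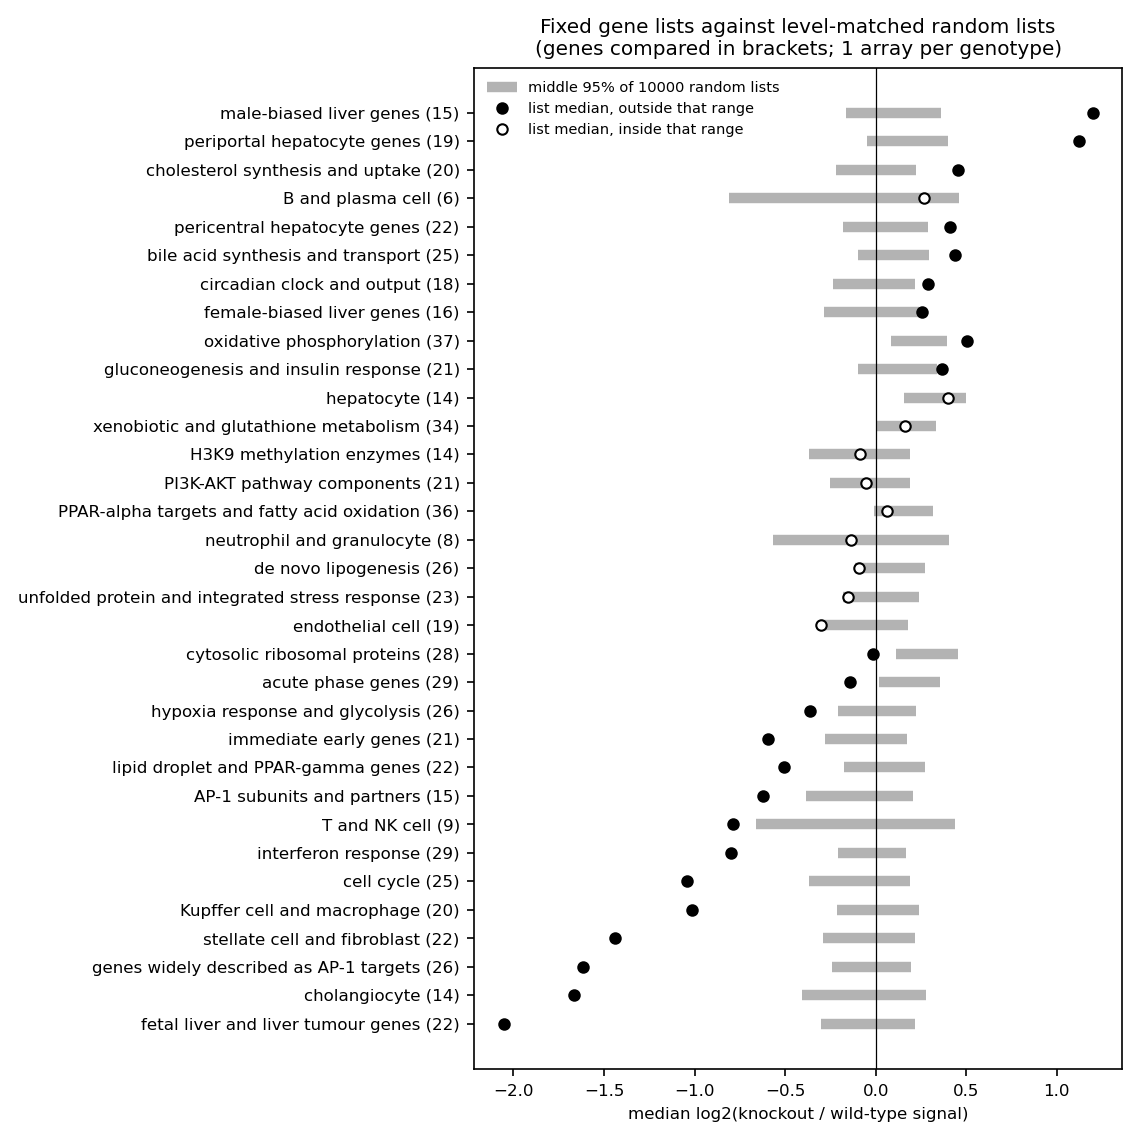
Median log2 ratio of knockout over wild-type signal (horizontal axis) of each list with at least 5 measured genes, 1 array per genotype, as a dot, with the middle 95% of level-matched random lists as a grey bar. 14 of 33 lists lie below that bar and 9 above it, from -2.05 for fetal liver and liver tumour genes to 1.20 for genes known to be higher in male liver.

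Scaling on the hybridisation controls shifted the median of all genes by -0.14 and scaling on the poly-A controls by 0.19, so list positions are given relative to genes of similar signal. The random lists describe these arrays and hold no information on the spread between animals.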

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

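No test was run for the values in this part, and they were singled out after the data were seen. These signals stand outside the gene comparison and were higher in the knockout array than in the wild-type array. The array's 3 control probe sets for mouse 18S ribosomal RNA were 1.81-fold, 1.74-fold and 1.89-fold higher in the knockout array, and stayed higher under each scaling by a single factor, from 1.58-fold with the hybridisation controls to 2.15-fold with the poly-A controls. Of 2719 kept probe sets without a single gene name, 298 were at least 2-fold higher in the knockout array and 164 were at least 2-fold lower, whereas lower genes outnumbered higher ones among the named genes. Scaling on the hybridisation controls turned that balance, with 207 higher and 218 lower.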

How the results depend on the processing

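Scaling on hybridisation and on poly-A controls was chosen after seeing the data, as was the yardstick for list medians; the other alternatives were planned. No paired analysis was possible because each genotype has 1 array, and no array could be left out. Of 1798 values of named genes under the alternatives, 1726 differed from the main value by less than the SD between probe sets of a gene, and no gene past 2-fold turned its direction. List medians stayed within the half-width of the middle 95% of their random lists in 365 of 393 cases. Against the first yardstick, the SD of the random lists, 114 had moved and 2 had turned direction. Turns of direction were counted only for lists whose main median lay outside the middle 95%. Counts of higher and lower genes were 1296 and 2038 at 1.5-fold, 102 and 409 at 3-fold, and 210 and 564 with the filter at the 70th percentile, which compares fewer genes; higher genes numbered 250 with the floor at the 60th percentile and 707 with poly-A scaling. Poly-A scaling turned the acute phase median to 0.043 and the ribosomal one to 0.17, and moved those of PPAR-alpha genes to 0.24, xenobiotic genes to 0.35, oxidative phosphorylation to 0.69 and hepatocyte markers to 0.58, as a factor common to all genes does. Other medians that it turned above 0 included lipogenesis (0.09), unfolded protein response (0.03), PI3K-AKT (0.13) and H3K9 enzymes (0.10), lists inside the middle 95% in the main setting. Quantile normalization gave -0.32 for acute phase, -0.22 for ribosomal and 0.10 for hepatocyte genes; loess gave -0.37, -0.21 and 0.12, with 0.34 for oxidative phosphorylation. Without a filter the AP-1 target median was -1.32. With the filter at the 70th percentile it was -0.28 for cell cycle, -3.09 for fetal and tumour genes and -0.92 for fibroblast markers. Fetal and tumour genes stood at -2.80 with the floor at the 20th percentile and with no floor. The floor at the 60th percentile gave -0.48 for cell cycle, -1.73 for fetal and tumour genes, -0.81 for fibroblast, -1.10 for cholangiocyte and 0.00 for T and NK cell markers; a higher floor shrinks ratios of dim genes. Averaging probe sets gave 0.22 for cholesterol and -0.32 for acute phase genes. Without cross-matching probe sets the lipid droplet median was -0.82 and the bile acid median 0.65. Apart from the floors and the single factors, the cause was not tested. The call of lying outside the middle 95% was lost under at least 1 alternative for cell cycle, T and NK cell, cholesterol, gluconeogenesis, clock, female-biased and ribosomal lists, and gained for lipogenesis, PPAR-alpha and endothelial lists. Each other ranked list stayed outside, or stayed inside, under every alternative. Signal near background limits the dimmest genes: 49 of the higher and 129 of the lower genes rest on a floored value. With this floor and filter, a kept gene with a floored value on 1 array always passes 2-fold. For those genes, passing 2-fold thus follows from the settings, and the counts of 448 higher and 1048 lower genes were the same with no floor.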

Other observations

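The gene families below and all tests in this part were chosen after the data were seen, except the tests of scaling and of recruited against resident macrophage genes, which were set before their results were seen, though after the patterns they concern. The use of the macrophage comparison against a lower number of macrophages was also chosen after. Collagens, annexins, tubulins and S100 proteins were lower in the knockout array. Of 14 keratins, 4 were at least 2-fold lower, or 2 with scaling on the poly-A controls, and 1 higher, with a median of 0.03 that ranged from -0.10 to 0.21 over the scalings. Of 10 claudins, 3 were lower and 0 higher, with a median of -0.21; both medians lay inside the middle 95% of random lists. Of 21 measured collagens, 11 were at least 2-fold lower, including the basement membrane chains Col4a1 (-2.44) and Col4a2 (-1.77) and the microfibrillar Col6a2 (-2.48). All 9 annexins had negative ratios, 6 of them past 2-fold, with a median of -1.71. Of 9 tubulins, 6 were at least 2-fold lower, and S100 proteins were lower in 5 of 8 cases. Of 15 measured genes of the MHC region, 6 were at least 2-fold lower and 0 higher, with a median of -0.71. The class II genes H2-Eb1 (-2.11) and H2-Aa (-1.63) had the lowest ratios and the class I gene H2-Q10 (0.22) the highest. Of 17 chemokines, 5 were at least 2-fold lower, 2 higher, with a median of -0.52. The monocyte attractant Ccl2 (a bound of -2.89) had the lowest ratio, and Cxcl13 (2.12), which attracts B cells, the highest.

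Families of detoxifying enzymes were looked at one by one, and differences between families were not tested. Of 10 measured Cyp2c genes, 5 were at least 2-fold higher, with a median of 1.09, and so were 3 of 7 Cyp2d genes, but 1 of 7 with median centring or scaling on the hybridisation controls. The carboxylesterases Ces1e (2.41) and Ces2a (2.15) were higher and Ces5a (-1.75) was lower. Glutathione transferases had 2 higher and 3 lower of 17, UDP glucuronosyltransferases 3 and 1 of 10, and the Cyp4a and Cyp4f genes 1 and 3 of 8, with medians inside the middle 95% of random lists. Scaling on the hybridisation controls gave 2 higher and 2 lower UDP glucuronosyltransferases. Family medians kept their sign under every scaling run for collagens, annexins, tubulins, S100 proteins, claudins, chemokines, MHC genes, Cyp2c, Cyp2d and carboxylesterases. The 38 proteasome subunits all lay within 2-fold, with a median of 0.05 that ranged from -0.09 to 0.23 over the scalings.

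Fibroblast, bile duct and liver tumour genes were lower in the knockout array. A dilution of all non-hepatocyte RNA by hepatocytes would lower every other cell type alike, if hepatocytes expressed none of the genes. On these arrays the endothelial median exceeded the bile duct median by 1.36 (95% bootstrap interval over genes 0.84 to 1.61), so these lists were not lowered alike. They were picked for this comparison after their medians were known, so the interval describes these genes and is no independent test of dilution. Expression of the genes in hepatocytes was not tested either, so dilution is not decided. Scaling or a signal-dependent bias is argued against: genes of similar signal would share it, yet the fibroblast, bile duct and tumour lists each had a median below all of their random lists. Scaling by a single factor moves a list and its random lists alike, so it could not change that rank. Over 6 scalings the highest median of these lists was -1.25. A hypothesis is that the Kdm3a knockout liver held less of a ductular, fibrotic or early tumour component, which may include a different amount of lesion in the piece sampled. With 1 array per group, a difference between animals or tissue pieces unrelated to Kdm3a cannot be told apart from the genotype.

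Macrophage genes went both ways. In further genes, listed after these markers but before their own values were seen, resident Kupffer genes had a median of 0.19 over 11 measured genes, with Fcna at 1.04 but Cd207 at a bound of -2.01, and recruited macrophage genes had -1.78 over 11, with Clec7a at -2.33 and Cx3cr1 at -2.28. Fewer macrophages of every kind would lower both lists alike if macrophages alone expressed these genes. The medians of the lists differed by 1.97 (95% bootstrap interval over genes 1.20 to 2.45). This cannot decide the question, because other cells also express some of the genes, among them Id3, whose ratio was the resident median. Fewer macrophages of every kind and fewer recruited macrophages both stay open. Error of single probe sets is argued against for the lower markers: such errors are independent between genes and enter the random lists too, yet over 6 scalings the highest median of the macrophage markers was -0.83, below all random lists. For the higher markers Cd163, Marco and Timd4 it stays open, since 1 of these 3 had several kept probe sets, too few to decide. The difference of 1.97 is consistent with a shift from recruited towards resident macrophages, as a hypothesis, although other cells also express several genes of either list, such as Id3, Cd9 and Ctsb.

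Periportal and male-biased hepatocyte genes were higher in the knockout array. Pericentral and female-biased genes were higher by less, with medians of 0.41 and 0.26. Animals of different sex are argued against: the largest absolute log2 ratio of 3 Y-linked genes, each read by its brightest probe set and above the floor on both arrays, was 0.235. A second probe set of Uty above the floor stood at -0.60, which is also within 2 SD between probe sets of a gene (SD 0.446). Tissue taken at different times of day stays open. The median of 4 dawn clock genes exceeded that of 6 dusk clock genes by 0.54. Its 95% bootstrap interval over genes, -0.74 to 1.27, was too wide to decide. Dawn genes ran from -0.61 for Clock to 1.35 for Nfil3, and dusk genes from -0.45 for Dbp to 0.51 for Ciart. No biological explanation was tested for this pattern. Age and hormonal state of the animals are not stated in the labels used here and stay open.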
